A study of Mus musculus with 2 samples.

How the data were processed

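The study measured monomethylation of lysine 4 of histone H3 (H3K4me1), a chromatin mark of enhancers and of the sequence beside promoters, by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was whole liver from mice of the strain B6NTac;B6NCrl/Lap on the day of birth. Per the labels, 2 biological replicates were made, each from livers of pooled male and female pups. Replicate 1 pooled 15 mice and had 1 technical replicate. Replicate 2 pooled a number of mice that the labels do not give and had 2 technical replicates. There is 1 group (postnatal day 0 liver), so the design holds no comparison between conditions. The replicate numbers are the ones in the labels.

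The authors deposited 4 peak lists on the mm10 build: the peaks of replicate 1, the peaks of replicate 2, a list called on the alignments of both replicates together (the pooled list), and a list of replicated peaks. Peaks were therefore called by the authors both per replicate and on pooled alignments. The aligner, the peak caller, its version and the rule by which a peak counts as replicated are not given in the sources used here. Each deposited list gives, for every peak, the authors' fold enrichment over control, a linear ratio. This ratio was used only to describe, rank or filter peaks within a list. Each deposited list also gives the authors' −log10 of the p-value and of the q-value per peak. The 2 further input files named beside each list have no stated role. The deposited texts that describe the files were read for these facts and hold no measurement. The lists hold no read counts, so the depth of each library is unknown, no counting interval can be given, and a region without a peak may hold signal below the authors' threshold.

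Coordinates were compared with the GRCm38.p6 assembly, the sequence that mm10 names, and every peak lay within the length of its chromosome. Genes came from the protein-coding models of GENCODE M21. Gene results used 21728 symbols on autosomes and X, and the transcription start site (TSS) of a gene was its annotated 5′ end. Promoters and distal peaks were defined from the start sites of all transcripts of protein-coding genes. Coordinates are 1-based. Calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

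The replicated list was the main peak set, and values per replicate came from each replicate's own list. Replicate overlap was the share of peaks with at least 50% of their length covered by the other replicate's peaks, against 100 circular shifts within each chromosome (one-sided). Genomic location was the share of peak bases in promoters (1 kb on each side of a TSS), other exons, introns and intergenic sequence, against 100 circular shifts (two-sided). The TSS profile was the share of TSSs covered in bins of 250 bp within 5 kb. Its ratio sets the 2 bins at the TSS against the highest other bin. The promoter's CpG content was the observed over expected CpG frequency of the 500 bp on each side of the TSS, and CpG-rich and CpG-poor promoters are the highest and lowest 25% of genes.

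For 29 gene lists, the median over members of the bases covered within 10 kb of the TSS was set against 10000 random lists matched on gene length decile (two-sided, Benjamini-Hochberg over the lists), a permutation of list membership. Genes were drawn without repeats, except where a list had more than 50 members in a decile. The unions of the liver, blood and nonparenchymal lists were each compared with the other-tissue lists by permutation of gene labels with 100000 resamples, over 3 comparisons. Genes are not replicates, so these p-values describe lists in these pools of livers and not the spread between animals. Replicated peaks were joined across gaps of up to 3 kb into domains, and those with at least 10 kb covered were counted. For motifs, hits per kb on both strands in peaks over 2 kb from any TSS were compared with sequence of the same length 5 kb away in no peak. This ratio was divided by that of the consensus read backwards. The log2 value per chromosome was tested by flipping signs over chromosomes with 100000 resamples, and 9 motifs were fixed, of which those with fewer than 6 usable chromosomes were not tested. That minimum was set after a first run of the motif test had been seen, because fewer chromosomes cannot give a p under 0.05. The consensus sequences were CAAAGTYCA for HNF4A, TGTTTAC for FOXA, TTRCGYAA for CEBP, GTTAATNATTAA for HNF1, AGATAAS for GATA, GAGGAAGT for PU.1, RTTGCCATGG for RFX, CTATTTWTAG for MEF2 and CAGCTGCTG for MYOD.

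The gene lists, motifs, tests and alternatives were fixed before the data were examined, except the alternatives named as chosen after seeing the data. Genes are named by a fixed rule: for each liver, blood and nonparenchymal list the 2 members with most covered bases (with cover in both replicates) and the 1 with the fewest, for each other list the 1 with most, the genes at the 10 domains with most covered bases, and Alb, Afp, Hnf4a, Cyp7a1 and Gata1. Ties were broken by symbol. The erythroid gene Ahsp was not found in the annotation. The alternatives were each replicate's own list in place of the replicated list, q of 0.01 or less, fold enrichment of at least 4, the pooled list, other windows around the TSS, random lists matched on promoter CpG decile and length tertile, gaps of 12.5 kb for domains, and motif flanks 20 kb away.

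The list test was tested on simulated data in which the 21728 genes were permuted within length deciles. Cover in the changed lists was multiplied by a factor and then raised by a constant that grew with the factor. The planted effects were thus larger than the factors alone. With a factor of 3 in 28 genes, the list passed in 16 of 20 runs, and with a factor of 2 in 18 genes it passed in 6 of 20 runs. With a factor of 1.5 in 18 genes it passed in 1 of 20 runs, and 3 of 500 tests of unchanged lists passed. On simulated sequence with the GATA consensus planted at 1.5 times its background rate, the motif step recovered a fold of 1.46, and for MEF2 planted at 2 times it recovered 2.20. The lowest adjusted p for a motif that was not planted was 0.393 there. Simulated bases were drawn independently, so a consensus that was not planted and its backwards form had the same expected rate. The simulation thus cannot show how the backwards control behaves with the base order of real sequence.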

Results

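H3K4me1 was mapped in 2 pools of newborn mouse liver (postnatal day 0), an organ that at this age holds hepatocytes together with blood-forming cells. The replicated list held 111716 peaks that covered 64.2 Mb, or 2.51% of the assembled autosomes and X. Their median width was 434 bp and the median of the authors' fold enrichment was 3.21, with a maximum of 9.95. Replicate 1 had 176493 peaks over 74.6 Mb and replicate 2 had 164297 peaks over 70.5 Mb. The pooled list had 148025 peaks. Each replicated peak was present in the pooled list with the same coordinates, and 94266 of the 111716 touched a peak in both replicates' own lists. A fold enrichment of at least 4 was given to 17.8% of the replicated peaks. Read depth is unknown, because the lists hold no counts.

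The only comparison between samples was that of the 2 replicates. Of the replicate 1 peaks on autosomes and X, 48.0% (84755 of 176488) had at least 50% of their length covered by replicate 2, against a mean of 2.89% and a maximum of 3.21% for shifted peaks. In the other direction the share was 52.1% (85519 of 164294), against 3.05% for shifted peaks. The one-sided permutation p was 0.0099 in both directions, the smallest that 100 shifts can give. The Jaccard index of covered bases was 0.384, against 0.0157 after shifting. Sharing rose with enrichment in the 5 ranges examined. Among replicate 1 peaks it was 31.9% below a fold enrichment of 2.5 and 92.9% at 5 or above. In replicate 2 the shares were 33.2% and 92.9%. Covered bases around the TSSs of 21728 genes had a Pearson correlation of 0.959 and a Spearman correlation of 0.955 between replicates. Over 257109 windows of 10 kb the Pearson correlation was 0.947 and the Spearman correlation 0.828, with 72.0% of windows empty in both replicates. These correlations are across genes or windows, which are not independent replicates.

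Peaks lay at promoters and in genes more often than shifted peaks did. Promoters, defined as 1 kb on each side of a TSS, held 21.1% of peak bases, against 4.07% ± 0.15 (SD over 100 shifts), a ratio of 5.18. Exons outside promoters held 4.11% (ratio 1.43) and introns 48.9% (ratio 1.37). Intergenic sequence held 25.9%, against 57.3% after shifting (ratio 0.452). The two-sided permutation p was 0.0198 for each location, the smallest that 100 shifts can give. Of the replicated peaks, 19.5% had their midpoint within 1 kb of a TSS and 36.6% lay between 10 and 100 kb away.

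Around the TSS, peak cover formed a trough with a shoulder on each side. Over all genes 14.5% of TSSs were covered at the start site itself, 22.4% in the bin at -750 bp and 26.2% in the bin at 750 bp downstream, so the ratio of the TSS to the highest bin was 0.554. The trough was deep in ribosomal protein genes, which are transcribed in all cell types, where 11.7% of 28 TSSs were covered at the start and 71.1% in the bin at 1250 bp. In cell cycle genes the values were 6.5% and 50.6% (bin at 1500 bp, 16 genes). CpG-rich promoters had 11.7% at the TSS and 43.8% at the highest bin (ratio 0.266), and CpG-poor promoters had 4.62% and 4.54% (ratio 1.02, and 0.871 to 1.05 over the alternatives). Genes of the other-tissue lists (muscle, neuron, lung, pancreas, intestine, kidney, keratinocyte and germ cell genes) had no trough in the replicated list, with 18.8% of 83 TSSs covered at the start and 16.8% at the highest other bin (ratio 1.12). Their ratio was 1.01 in replicate 1's own list and 1.06 in replicate 2's, and it fell to 0.888 at a fold enrichment of at least 4. Hox genes, which pattern the body axis, had 38.1% at the TSS and 36.2% beside it in the replicated list (ratio 1.05). The side of 1 on which the Hox ratio lay differed between replicates, with 1.34 in replicate 1's own list and 0.834 in replicate 2's, and it was 0.838 at q of 0.01 or less. Liver lists had a ratio of 0.518 and blood lists 0.939. These ratios are descriptive and the differences between gene sets were not tested here. The ratio over all genes was 0.590 in replicate 2's own list and 0.557 in replicate 1's.

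**Figure D1:**
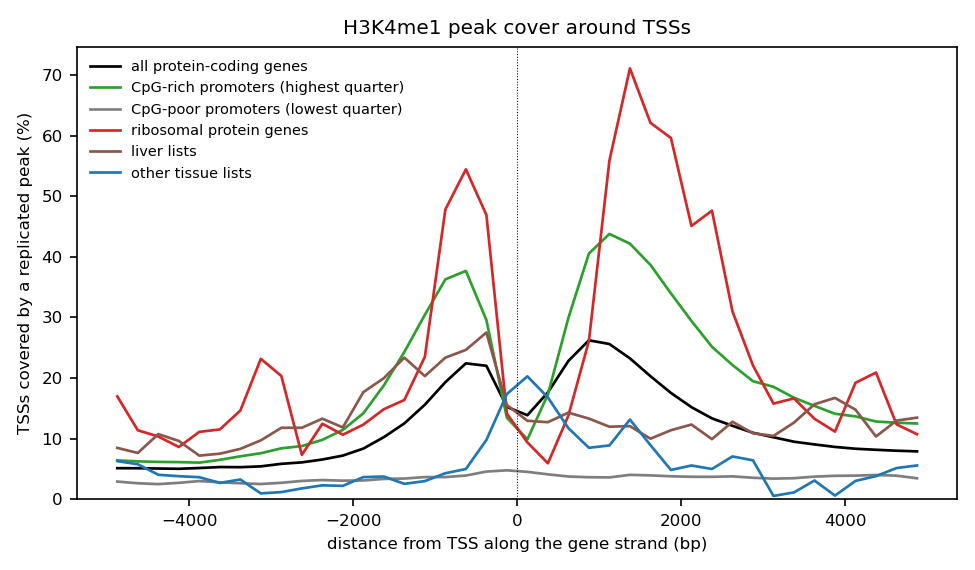
Share of TSSs (%) covered by a replicated peak in bins of 250 bp, against the distance from the TSS along the gene's strand (bp), for 6 sets of genes drawn as lines. Over all genes the line has a trough of 14.5% at the TSS and a shoulder of 26.2% downstream, and in ribosomal protein genes the shoulder reaches 71.1%.

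Gene lists were compared to ask which groups of genes carried most H3K4me1 around their TSSs. A protein-coding gene had a median of 1126 bp covered within 10 kb of its TSS, and 30.5% of genes had no covered base. Genes of all liver lists had a median of 1687 bp (127 genes) against 438 bp in the other-tissue lists (83 genes), and the two-sided permutation test gave an adjusted p of 3e-05 (unadjusted 1e-05, the smallest that 100000 resamples can give). Blood list genes had a median of 1728.5 bp (66 genes, permutation adjusted p = 9e-05 against other tissue). Genes of the nonparenchymal cells of liver (Kupffer cells, endothelium, stellate cells and cholangiocytes) had 743 bp (49 genes) and did not differ detectably from other tissue (permutation adjusted p = 0.305). In replicate 1's list the medians were 2322 bp for liver, 2098 bp for blood and 527 bp for other tissue, and in replicate 2's they were 2229, 2203 and 633 bp. With peaks limited to a fold enrichment of at least 4, the medians of liver, blood and other-tissue genes were all 0 bp. A difference of medians cannot be tested at that floor, so this setting does not show whether the differences held.

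Of 29 lists, 3 passed an adjusted p of 0.05 against random lists matched on gene length. Blood stem and progenitor genes had a median of 3390 bp over 12 genes, against 1116 bp in random lists (permutation adjusted p = 0.0406). Ribosomal protein genes had 2906 bp over 28 genes, against 672 bp (permutation adjusted p = 0.0116), and 7 members lay in the top 10% of all genes, led by Rps14 with 9166 bp, whose peak of highest enrichment lay in an intron of Ndst1. Olfactory receptor genes, a large family used in sensory neurons, had a median of 0 bp against 798 bp (permutation adjusted p = 0.0058), and 1067 of 1092 had no covered base. Olfr692 had the most, 1453 bp, with its peak of highest enrichment in an exon of Fam160a2. For olfactory receptor genes the unadjusted permutation p of 0.0002 is the smallest that 10000 random lists can give. Hepatocyte transcription factors had 2990 bp over 18 genes against 1122 bp and did not pass (permutation adjusted p = 0.0536). The calls depended on how random lists were matched. Against lists matched on promoter CpG content, 5 lists passed, all above the random lists: hepatocyte transcription factors, plasma proteins, glucose and glycogen metabolism, blood stem and progenitor genes and megakaryocyte genes (permutation adjusted p = 0.0383 for each). Ribosomal protein genes (permutation adjusted p = 0.438) and olfactory receptor genes (permutation adjusted p = 1.0) did not pass there. The olfactory receptor median of 0 bp lies at the floor, and it fails to pass when random medians are often 0 bp as well. Matching on CpG content therefore does not show whether the cover of olfactory receptor genes was low for their promoters. Blood stem and progenitor genes lost their call in 7 of 11 alternatives, among them q of 0.01 or less (permutation adjusted p = 0.0609) and windows of 50 kb (0.191), and the adjusted p over all alternatives was 0.0155 to 1.0. That of hepatocyte transcription factors was 0.0213 to 1.0, and they passed in 6 of 11 alternatives.

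**Figure D2:**
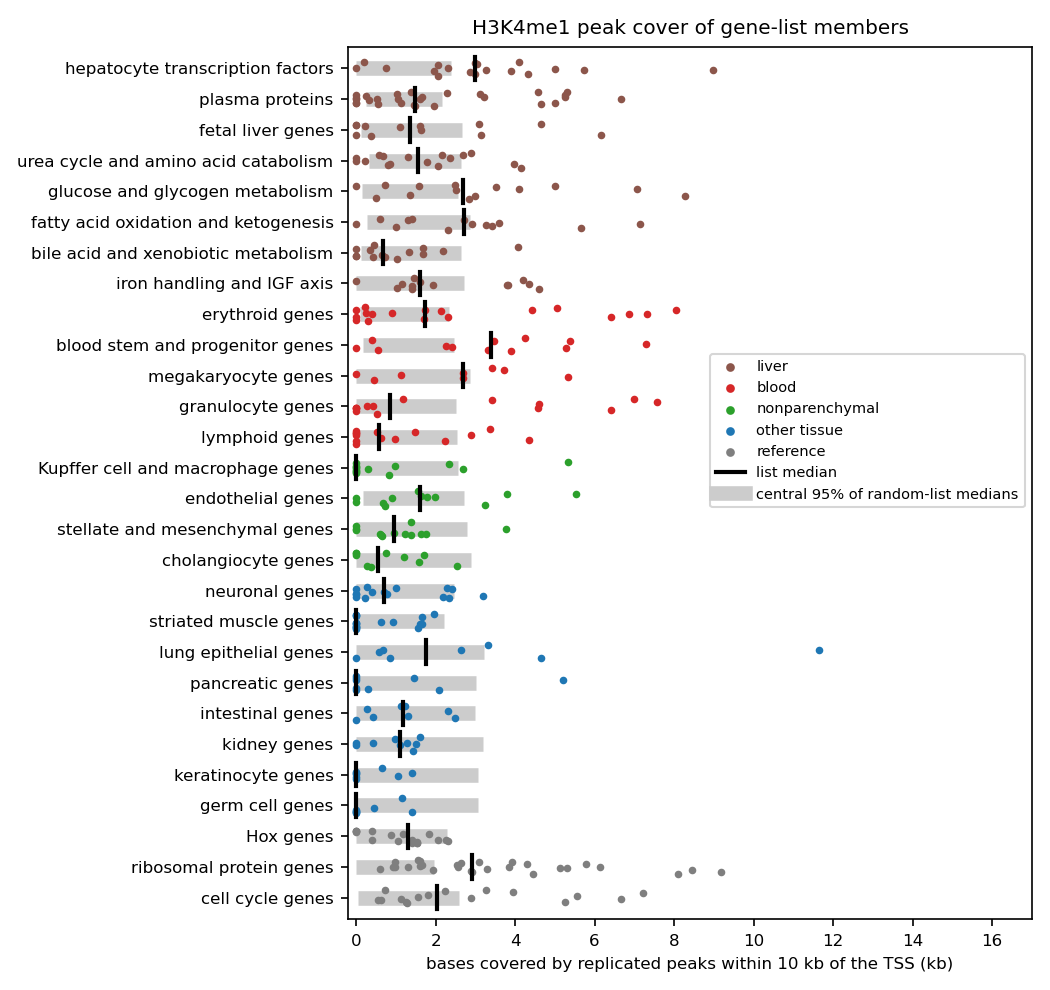
Bases covered by replicated peaks within 10 kb of the TSS (kb) for each member of 28 gene lists (points, colored by class), with the list median (black bar) and the central 95% of medians of random lists matched on gene length (grey). The medians of blood stem and progenitor genes (3390 bp) and of ribosomal protein genes (2906 bp) lie to the right of the grey range, as do those of hepatocyte transcription factors and glucose metabolism genes, which did not pass after adjustment, and olfactory receptor genes are not drawn.

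Among hepatocyte transcription factors, 17 of 18 genes had a covered base. Rxra, a nuclear receptor partner, had 8987 bp covered in the replicated list (8849.5 ± 678.1 bp over the replicates' own lists, SD, n = 2), and Cebpa, a regulator of hepatocyte differentiation, had 5722 bp (6034.5 ± 275.1 bp, n = 2). The peak of highest fold enrichment (5.20) within 10 kb of the annotated 5′ end of Rxra lay in an intron at chromosome 2, 27681432 to 27683977. For other genes of the lists too, the peak of highest enrichment is the highest within 10 kb of the annotated 5′ end. Hnf4a, a master regulator of hepatocytes, had 0 bp around its annotated 5′ end at position 163506808 of chromosome 2 (0 and 225 bp in the replicates' own lists). Around the Hnf4a transcript start at 163550083, a site chosen after seeing the data as the best covered, 6604 bp were covered, and 14.4% of the gene body with 10 kb on each side was covered. List values count peaks around annotated 5′ ends, so genes transcribed from an internal promoter can be understated.

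The other liver lists had medians of 686 to 2708 bp. Both replicates' own lists gave higher medians than the replicated list for plasma proteins (2456 and 1972 bp against 1469 bp). The same held for bile acid genes (1031 and 1007 bp against 686 bp). In replicate 1's own list these 2 medians were over 1.5 times those of the replicated list. Among plasma protein genes, 5 of 28 lay in the top 10% of genes and 5 had no covered base. Complement C3 had 6664 bp and the lipoprotein gene Apoc3 5292 bp, while Apob had 0 bp in the replicated list (248 and 473 bp in the replicates' own lists). Alb, which encodes serum albumin, had 550 bp in the replicated list but 950 bp in replicate 1's and 1252 bp in replicate 2's, and the fetal albumin homologue Afp had 1623 bp. The only replicated peak within 10 kb of the Alb TSS lay upstream, in intergenic sequence at chromosome 5, 90452884 to 90453433, with a fold enrichment of 2.79. In glucose and glycogen metabolism (median 2684 bp, 14 genes, permutation adjusted p = 0.196), the fructose kinase gene Khk had 8262 bp and the liver glycogen phosphorylase gene Pygl 7074 bp, while Ppargc1a had 0 bp (879 and 0 bp in the replicates' own lists). In fatty acid oxidation and ketogenesis (median 2708 bp, 13 genes, permutation adjusted p = 0.310), Cpt1a, which encodes the enzyme that carries fatty acids into mitochondria, had 7134 bp, Ehhadh 5656 bp and Pdk4 0 bp (390 and 1179 bp in the replicates' own lists). The Khk window also holds another gene's TSS, and its peak of highest enrichment lay in an exon of Emilin1. In the urea cycle and amino acid list (median 1547 bp, 16 genes, permutation adjusted p = 0.829), Asl had 4141 bp, Ass1 3975 bp and Arg1 0 bp (1016 and 662 bp in the replicates' own lists). Bile acid and xenobiotic genes had a median of 686 bp over 14 genes (permutation adjusted p = 0.668). There the bile acid enzyme genes Cyp8b1 and Cyp7a1 had 4082 bp and 1694 bp, Cyp27a1 had 2194 bp, and Cyp2c29 had 0 bp in all 3 lists compared. Fetal liver genes had a median of 1348 bp over 12 genes (permutation adjusted p = 0.850), led by Igf2bp3 with 6162 bp and Ahsg with 4654 bp, while Gpc3, on the X chromosome, had 0 bp (410 and 351 bp in the replicates' own lists). The iron and IGF axis list had 1617 bp over 13 genes (permutation adjusted p = 0.706), led by Irs2 with 4602 bp and Insr with 4348 bp, while Hfe2 had 0 bp (691 and 277 bp in the replicates' own lists).

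In the erythroid list (median 1728 bp, 18 genes, permutation adjusted p = 0.651), 5 members lay in the top 10% of genes. Tal1, a transcription factor of blood formation, had 8037 bp (7388 ± 222 bp over replicates, SD, n = 2) and Fech, the last enzyme of heme synthesis, had 7313 bp. Gata1 and Alas2, which lie on the X chromosome, had 0 bp in the replicated list. In the replicates' own lists Gata1 had 0 and 195 bp and Alas2 382 and 519 bp. In the stem and progenitor list, Runx1 had 7301 bp (6720.5 ± 276.5 bp over replicates, SD, n = 2) and Gata2 5373 bp, while Mecom had 0 bp in all 3 lists. Megakaryocyte genes had a median of 2692 bp over 8 genes (permutation adjusted p = 0.310), led by the platelet receptor gene Gp1ba with 5339 bp and Itga2b with 3725 bp, while Mpl had 0 bp in all 3 lists. The Gp1ba window holds 2 other TSSs, and its peak of highest enrichment lay in an exon of Slc25a11. In the granulocyte list (median 858 bp, 14 genes, permutation adjusted p = 0.994), the neighbouring protease genes Prtn3 and Elane had 7559 bp and 7000 bp, partly from the same peaks, and Ctsg had 0 bp in all 3 lists. The Prtn3 peak of highest enrichment lay in an exon of Plppr3. In replicate 1's own list the granulocyte median was 1431 bp. Lymphoid genes had a median of 577 bp over 14 genes (permutation adjusted p = 0.706), and 919.5 and 805.5 bp in the replicates' own lists. They were led by Cd79a with 4340 bp and Cd79b with 3368 bp, while Cd19 had 0 bp (485 and 204 bp in the replicates' own lists). The peak of highest enrichment in the Cd79a window lay in an intron of Arhgef1, and that in the Cd79b window in an exon of Scn4a.

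Nonparenchymal and control lists were lower or mixed, and none of those named in this paragraph passed the list test. Kupffer cell and macrophage genes had a median of 0 bp, with 8 of 14 members uncovered (permutation adjusted p = 0.310), and medians of 300.5 and 204.5 bp in the replicates' own lists. Cd68, whose window holds 2 other TSSs, had 5328 bp there, Csf1r 2698 bp (2948 and 4105 bp in the replicates' own lists) and C1qb 0 bp in all 3 lists. Endothelial genes had a median of 1600 bp over 12 genes (permutation adjusted p = 0.706), with Stab1 at 5527 bp, Pecam1 at 3791 bp and Stab2 at 0 bp (399 and 212 bp in the replicates' own lists). The peak of highest enrichment in the Pecam1 window lay in an exon of Milr1. Stellate and mesenchymal genes had 952 bp over 13 genes (permutation adjusted p = 0.751), led by Reln with 3758 bp and Ngfr with 1767 bp, while Dcn had 0 bp in all 3 lists. Cholangiocyte genes had 559 bp over 10 genes (permutation adjusted p = 0.668), led by Prom1 with 2538 bp and Sox9 with 1719 bp, while Krt19 had 0 bp (239 and 209 bp in the replicates' own lists). The medians of the striated muscle, pancreatic, keratinocyte and germ cell lists were 0 bp (permutation adjusted p = 0.394, 0.706, 0.651 and 0.394). In the lists of replicates 1 and 2 they were 427 and 202 bp for muscle, 283.5 and 204.5 bp for keratinocyte and 114.5 and 220 bp for germ cell genes, and 0 bp in both for pancreatic genes. For each list of this paragraph except endothelial and cell cycle genes, the central 95% of random medians began at 0 bp. Cover below that of random lists could not pass there, so the test could not show a deficit in those lists, Kupffer cell genes included. Neuronal genes had 699 bp, lung epithelial genes 1750 bp, intestinal genes 1191 bp and kidney genes 1115 bp (permutation adjusted p = 0.706, 0.706, 0.910 and 0.836). In 1 replicate's own list the lung median was 2881 bp (replicate 1), the cholangiocyte median 919 bp (replicate 2) and the stellate median 1479 bp (replicate 2), over 1.5 times the values above. The members with most covered bases were Dlx2 for neurons (3201 bp), Tnni2 for muscle (1953 bp), Cela1 for pancreas (5200 bp), Satb2 for intestine (2498 bp), Aqp2 for kidney (1600 bp), Krt1 for keratinocytes (1415 bp) and Ddx4 for germ cells (1401 bp). The lung gene Ager had 11644 bp, but its window holds 4 other TSSs and its peak of highest enrichment lay in an exon of Gpsm3. That of Krt1 lay in an exon of Krt77. Of the other genes named for their cover, the windows of Apoc3 and Hoxd9 hold 2 other TSSs and those of Asl, Ehhadh, Tnni2, Ddx4 and Mcm2 hold 1. Hox genes had a median of 1294 bp (permutation adjusted p = 0.706), led by Hoxd9 with 2303 bp (1456 and 2255 bp in the replicates' own lists), and cell cycle genes 2024 bp (permutation adjusted p = 0.599), where Mcm2, a replication licensing gene, had 7225 bp.

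Peaks joined into 43278 domains, of which 502 had at least 10 kb covered and held 12.2% of the bases in domains. The domain with most covered bases lay over Mtss1, a gene of actin and membrane organisation, at chromosome 15, 58973177 to 59083607. Its 73 peaks covered 75652 bp in the replicated list, and 72102 and 73451 bp of it were covered in the replicates' own lists. The domain at Zmiz1, a transcriptional coregulator gene, followed at chromosome 14, 25447169 to 25547339, with 71212 bp covered and a highest fold enrichment of 8.83. Next came domains at Cmip (60779 bp), Zfpm1 (49525 bp), Ago2 (39846 bp) and Bcl2l1 (38751 bp). The Zfpm1 domain also lies in the overlapping gene Gm20388. Zfpm1 encodes a cofactor of GATA factors in erythroid cells and megakaryocytes, and Bcl2l1 encodes an inhibitor of cell death needed by maturing red cells. Elmsan1, Myh9, Klf13 and Actn4 lay at the remaining domains of the first 10, with 36304 to 38596 bp covered. The domain in Klf13 does not reach the annotated TSS of Klf13. Its nearest TSS is that of E030018B13Rik, a gene whose coordinates lie within those of Klf13. With the wider of the gaps joined, 1381 domains reached 10 kb, and with peaks of fold enrichment of at least 4 the count was 73.

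**Figure D3:**
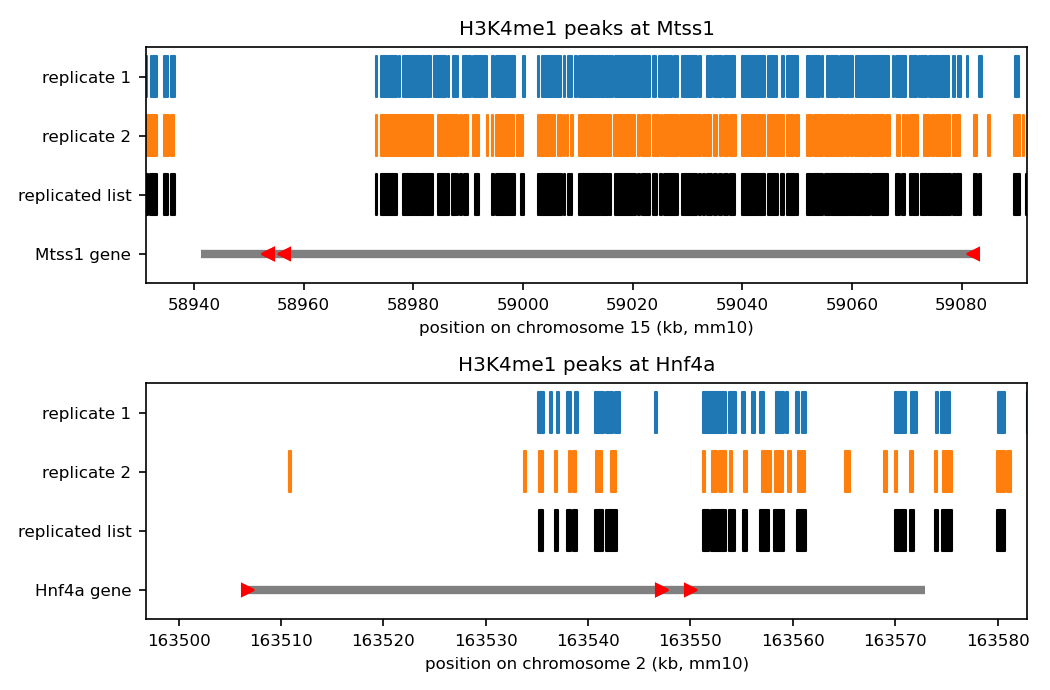
Peaks of each replicate and of the replicated list (bars) along Mtss1 and Hnf4a with 10 kb on each side, by position (kb, mm10), with the gene in grey and protein-coding transcript starts as red arrowheads. Mtss1 holds dense peaks in all 3 lists, and Hnf4a has replicated peaks around its downstream starts near 163550083 but none within 10 kb of its 5′ end.

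The chromosomes differed in peak density. Autosomes had 33.3 (chromosome 14) to 75.6 (chromosome 11) peaks per Mb, with a Spearman correlation of 0.904 between peak and gene density over 19 chromosomes, which is descriptive. Chromosome X had 498 peaks, or 3.05 per Mb, a ratio of 0.0656 to the autosomes. X makes up 6.39% of the assembled sequence and held 0.446% of the peaks. The ratio was 0.104 in replicate 1's list and 0.0813 in replicate 2's. With a fold enrichment of at least 4, 20 peaks remained on X and the ratio was 0.0148. Genes on X had a median of 0 bp covered, against 1228 bp on autosomes. No peak was listed on Y.

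**Figure D4:**
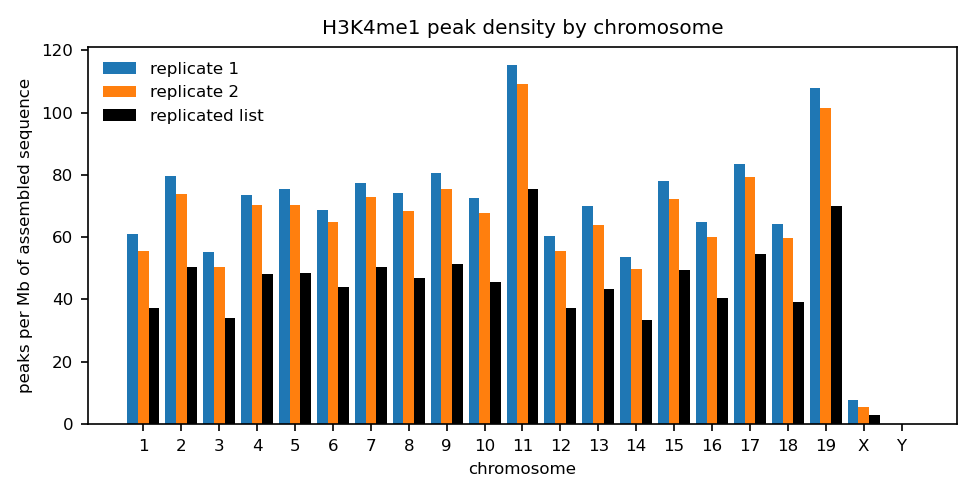
Peaks per Mb of assembled sequence (bars) for each chromosome in the lists of replicate 1, replicate 2 and the replicated peaks. In the replicated list X has 3.05 peaks per Mb, while autosomes have 33.3 to 75.6.

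Distal peaks held more consensus sites of the liver and blood transcription factors GATA, PU.1, FOXA, HNF4A and CEBP than the sequence beside them. The comparison used 76353 peaks over 2 kb from any TSS, with a GC content of 49.0% against 45.2% in the flanks. GATA sites, bound by blood factors and by GATA4 in liver, were enriched on 20 of 20 chromosomes, with a log2 ratio of 0.74 ± 0.12 (SD over chromosomes) relative to the consensus read backwards (permutation adjusted p = 2.7e-05). PU.1 sites, bound by a myeloid and lymphoid factor, had 0.50 ± 0.21 on 20 of 20 chromosomes (permutation adjusted p = 2.7e-05). For the hepatocyte factors, FOXA had 0.47 ± 0.13 (20 of 20 chromosomes, permutation adjusted p = 2.7e-05), HNF4A 0.56 ± 0.34 (19 of 20, permutation adjusted p = 3.2e-05) and CEBP 0.96 ± 0.77 (18 of 20, permutation adjusted p = 3.2e-05). For FOXA, GATA and PU.1 the unadjusted p was 1e-05, the smallest that the resamples can give. For CEBP, whose consensus holds a CG, the log2 ratio was 0.51 ± 0.92 with a control that keeps the CG, chosen after seeing the data. With that control 17 of 19 chromosomes were higher, and the sign-flip permutation p was 0.0263, not adjusted over motifs. The CEBP result was thus much weaker with that control. MEF2, a muscle factor taken as a control motif, also passed (0.60 ± 1.11, 16 of 20 chromosomes, permutation adjusted p = 0.0357), and it passed in 4 of 6 alternatives, with log2 ratios of 0.96 without replicate 1 (18 of 20 chromosomes, permutation adjusted p = 5.3e-05), 0.66 without replicate 2 (permutation adjusted p = 0.000293), 0.87 in the pooled list (permutation adjusted p = 0.00156) and 0.71 with flanks 20 kb away (permutation adjusted p = 0.00343). It did not pass at q of 0.01 or less (log2 ratio 0.42, permutation adjusted p = 0.19) or at a fold enrichment of at least 4 (log2 ratio 0.62, permutation adjusted p = 0.165). Passing this test was thus not limited to the motifs chosen for liver and blood factors. Whether MEF2 factors act in cells of newborn liver was not tested. HNF1 passed on 37 hits in peaks over 7 usable chromosomes (log2 ratio 1.32, permutation adjusted p = 0.0364), and it also passed in the pooled list (log2 ratio 0.99, permutation adjusted p = 0.0277). It did not pass without replicate 1 (log2 ratio 1.07, permutation adjusted p = 0.141) or without replicate 2 (log2 ratio 1.33, permutation adjusted p = 0.0606), where the SD over chromosomes was 1.95 and 1.84 against 0.99. RFX did not pass (log2 ratio 0.67, 6 chromosomes, permutation adjusted p = 0.0951), and its log2 ratio was 0.03 without replicate 1 and 0.28 without replicate 2. MYOD, another muscle factor, could not be tested because 1 chromosome was usable. Its backwards consensus holds CG, unlike its consensus. Before division by the backwards consensus, its ratio of hits per kb in peaks over flanks was 1.59. That ratio was 1.64 for PU.1, 1.55 for CEBP, 1.53 for HNF4A, 1.45 for HNF1 and 1.32 for GATA. It was 1.27 for RFX, 1.23 for the control motif MEF2 and 1.19 for FOXA, the lowest of the motifs. These undivided ratios do not allow for the difference in GC content between peaks and flanks. Differences between motifs were not tested.

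**Figure D5:**
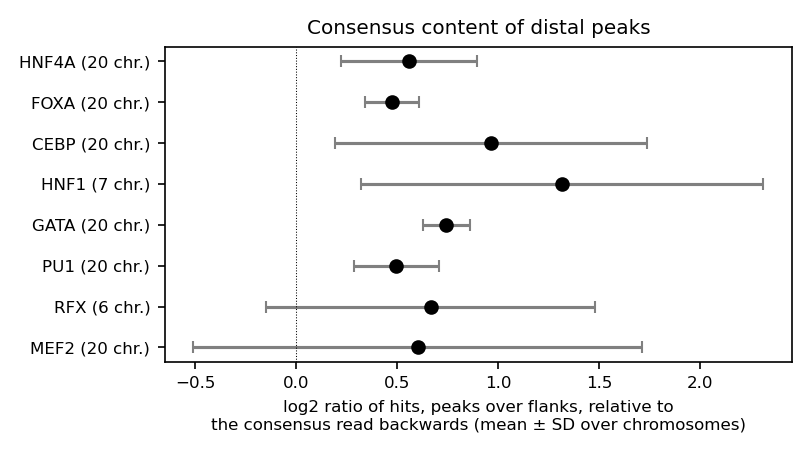
Log2 ratio of consensus hits per kb in distal replicated peaks over flanks, relative to the same ratio for the consensus read backwards, for 8 motifs (points, mean; bars, SD over the usable chromosomes). GATA, at 0.74 ± 0.12, and FOXA, at 0.47 ± 0.13, have the narrowest bars.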

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

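Alternatives on autosomal genes, on the best covered transcript start and with a CG-keeping control motif were chosen after seeing the data, as was the minimum of 6 chromosomes for a motif test. Leave-one-out used each replicate's own list, which was not possible for replicate overlap, since that needs both. No paired analysis was possible because there is 1 group. Replicate overlap (45.1% to 60.9% of replicate 1 peaks and 38.8% to 65.0% of replicate 2 peaks) and the promoter ratio (4.42 to 6.26) stayed past their tests under their alternatives. The liver against other-tissue difference did so except at fold enrichment of at least 4. There both medians were 0 bp, so the test could not decide. Without 1 replicate, the number of peaks was 164297 to 176493, the TSS ratio 0.557 to 0.590, domains 575 to 601, the X to autosome ratio 0.0813 to 0.104, lists past the threshold 4 and motifs 6. At fold enrichment of at least 4 the number of peaks was 19884, the TSS ratio 0.484, domains 73, the X ratio 0.0148 and lists 0. At q of 0.01 or less the X ratio was 0.0493. The wider gaps gave 1381 domains. Windows of 2 kb left 0 lists past the threshold and CpG-matched random lists gave 5, by their construction a comparison with genes of like promoters. For the other changes the cause was not tested.

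In these cases a list's median changed side of the random median, with no call in either setting. With windows of 2 kb these were plasma proteins (280 bp), fetal liver (578.5 bp), urea cycle (469 bp), endothelial (70 bp), lung (300 bp) and intestinal genes (0 bp). With CpG matching these were bile acid (685.5 bp), lymphoid (577 bp), kidney (1115 bp), Hox (1294 bp) and cell cycle genes (2024 bp). For fetal liver genes it also changed without 1 replicate (1322 to 1347 bp), at q of 0.01 or less (806.5 bp) and over gene bodies (3.16%). For bile acid genes it changed within 50 kb (4538 bp) and over gene bodies (5.50%). For intestinal genes it changed without 1 replicate (1156 to 1368 bp), within 50 kb (2630 bp), over gene bodies (1.57%) and at the best transcript start (1191 bp). Granulocyte genes changed without 1 replicate (833.5 to 1431 bp), at q of 0.01 or less (600.0 bp), on autosomes (857.5 bp) and at the best transcript start (882 bp), and stellate genes without 1 replicate (832 to 1479 bp). Where a range is given, the change occurred without replicate 1 alone, except for fetal liver genes, where it occurred without replicate 2 alone. Among the results for single lists, motifs, profiles and genes, 567 were classed as unchanged, 237 moved, 9 passed and 18 no longer passed. A tested result counted as unchanged when its call and direction stayed the same, even if its value changed. An untested value counted as moved when it changed by at least the SD between the replicates' own lists. Because depth is unknown, an uncovered base cannot be told from signal under the threshold.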

Other observations

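The tests in this part were chosen after the results they bear on were seen, except the scaling of X signal and the GATA comparison. On chromosome X, 21.6% of 948 genes had a covered base within 10 kb of the TSS, against 71.7% of autosomal genes, and no X gene lay in the top 10%. The X genes with most covered bases were Sash3 (3887 bp), Hcfc1 (3580 bp) and G6pdx (2380 bp), named after their values were seen. Sash3 is a lymphocyte signalling adaptor, Hcfc1 a transcriptional coregulator and G6pdx the first enzyme of the pentose phosphate pathway.

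The low number of peaks on X was weighed against 3 explanations. Gene density and promoter CpG content are argued against, since the lowest of 10000 autosomal lists matched on both had 57.4% of genes covered, against 21.6% on X. Selection of replicated peaks is argued against, since peaks per TSS on X relative to autosomes were 0.186 and 0.148 in the 2 replicates' own lists. A scaling of X signal remains open, though 1 uniform factor was not borne out across fold levels. At a fold enrichment of 3, the factor that equalises peaks per TSS on X and on autosomes was 0.613 (95% block bootstrap interval 0.577 to 0.641). It was 0.549 (0.512 to 0.573) at 2.5, 0.622 at 3.5 and 0.594 at 4, and up to 0.680 in replicate 1's own list, at 3.5. The factor at 2.5 minus that at 3 was -0.0643 (95% paired bootstrap interval -0.0723 to -0.0509), so 1 factor for all levels was not borne out. This interval was also wholly negative in both replicates' own lists and in the pooled list. For 3.5 and 4 against 3, the intervals in the replicated list spanned both signs. In replicate 1's own list the factor at 3.5 minus that at 3 was 0.0371 (0.0107 to 0.0389). Incomplete listing of weak peaks may lower the factor at 2.5, which the lists cannot show. Since the factor is fitted at each level, its lying between 0.5 and 1 shows only that lower X copy number, or 1 active X per cell, is not excluded. These cannot be separated, since both pools mix the sexes and the lists hold no control signal.

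Lower cover at the TSS than beside it was weighed against the GC content of the sequence. The trough deepened with GC, from a ratio of TSS to highest bin of 0.821 in the lowest GC quintile to 0.490 in the highest. Each of 7 fixed sets of genes was then compared with random lists matched on GC. Other-tissue genes (ratio 1.12 against a matched mean of 0.549, adjusted p = 0.0028), Hox genes (1.05 against 0.440, adjusted p = 0.0189) and blood genes (0.939 against 0.557, adjusted p = 0.0326) had shallower troughs, and ribosomal protein genes a deeper one (0.165 against 0.504, adjusted p = 0.0326), by two-sided permutation. Liver genes (0.517 against 0.549, adjusted p = 0.927), nonparenchymal genes (0.507 against 0.532, adjusted p = 0.927) and cell cycle genes (0.128 against 0.470, adjusted p = 0.0719) did not differ detectably from matched lists by permutation. The ratios of these sets had been seen when the test was chosen, and it was run on the replicated list alone. An earlier version of the ratio, over the mean of 4 bins between 500 and 1000 bp from the TSS, kept the departures of other-tissue genes (2.56 against 0.694, permutation adjusted p = 0.0007) and Hox genes (2.98 against 0.629, permutation adjusted p = 0.0007), where 0.0002 unadjusted is the smallest that 10000 lists can give. It did not keep those of blood genes (1.17 against 0.726, permutation adjusted p = 0.118) and ribosomal protein genes (0.330 against 0.688, permutation adjusted p = 0.127). The other-tissue and Hox genes thus argue against GC content as the whole source of the trough, while for the other 5 sets an effect of GC stays open. No biological explanation of the trough was tested, since the lists hold no measure of promoter activity.

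Hypotheses on domains and motifs gave 1 negative result and 1 small difference. Because Zfpm1 and Bcl2l1, at 2 of the first 10 domains, are used in blood cells, genes of the blood lists were asked to lie within 10 kb of a domain of at least 10 kb more often than liver genes. The shares were 1.52% of 66 blood genes and 3.15% of 127 liver genes, with a permutation p of 0.666, so the hypothesis was not borne out. Over all protein-coding genes the share was 2.37% (514 of 21728), and in the other-tissue lists it was 2.41%. The classes held 1 and 4 such genes, too few to resolve a small difference. The liver genes were Cpt1a, Irs2, Khk and Rxra and the blood gene was Vwf, all named after their values were seen. Distal peaks with the GATA consensus (10492 of 76353) had a median fold enrichment of 3.38, against 3.16 without it. Within deciles of peak width the median difference averaged 0.0312 (two-sided permutation p = 0.00599), but it was positive in 5 of 10 deciles, from -0.0466 to 0.210, so the direction did not hold across widths. The test was first run on means, which was not the statistic fixed beforehand, and gave 0.0284 (permutation p = 0.000999, the smallest that 1000 permutations can give), positive in 8 of 10 deciles.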
